A study of Mus musculus with 12 samples.

How the data were processed

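The samples were 12 tumours of 4T1 cells, with 50000 cells injected into the right flank of each mouse, per the labels' protocols. Antibody injections began on day 12, local RT in 5 fractions of 6 Gy began on day 13, and tumours were taken on day 22, which the series text places 4 days after the end of RT. Each sample's group and mouse number came from its title, and each mouse belonged to 1 group, so replicates were separate animals. RNA was extracted with an RNeasy kit, and biotin-labelled cRNA made from 6 ug of total RNA was hybridized to Affymetrix arrays of 45101 probe sets, per the labels' protocols.

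The values are probe set intensities on a linear scale, which the authors deposited after RMA (robust multi-array average) processing, per the submitters' processing notes, where its version is not given. RMA corrects the background, equalizes the distributions of the arrays and summarizes the probes of a set, so intensities are relative between arrays and a shift common to most genes would not be seen. The deposited intensities ran from 7.77 to 34130 and were turned into log2 values here, with no further normalization. Scan dates were not given in the sources used here, so no batch could be tested. Of the probe sets, 34945 were annotated to 1 gene, 932 to several, 9160 to none and 64 were controls. For each gene the probe set with the highest mean over all arrays was kept, which gave 18193 genes, and 13775 were tested, those whose third-highest value of 12 reached the 40th percentile of all values, a log2 value of 5.30. Probe sets with several genes or none were tested apart (3961 above that level) and are named nowhere. Values under that level lie near the low end of the array, so a gene with all 3 values of a group there is given as at least its difference from that level, and sizes that rest in part on such values (Ctsg, Cd28, Cd80, Tek and Gas2 among others) are uncertain.

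Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with a mean per group over all 12 arrays, which leaves 8 residual degrees of freedom, and Benjamini-Hochberg adjusted p-values under 0.05 counted as passed. Standard errors (SE) and 95% intervals are those of this fit, and the interaction is the change with 1D11 in irradiated tumours minus that in unirradiated tumours. Gene lists for immune cell types, stroma, the tumour cells, interferon, TGF-beta and stress responses and adjacent tissues were written before the data were examined. The 27 lists with at least 5 members above the filter (478 distinct genes) were tested with limma's camera at its preset correlation of 0.01, with camera's estimated correlation and with fry, which asks whether the members move on balance in 1 direction. List members with no annotated probe set were not analysed here.

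Genes to be named were fixed by a rule before the data were examined: up to 10 per direction with the largest change among those that passed and whose groups did not overlap (5 per direction and no such condition for the interaction), the 3 per direction with the smallest p where none passed, up to 4 members per list that passed, and a panel of 20 genes of TGF-beta signalling, immunity and proliferation. Some genes the rule gave, including several panel genes, were left out of the text. Outside the rule, and chosen after their values were seen as examples of a list, were Irf7, Cmpk2, Oasl2, Ccng1 and Pfkp for 1D11 against isotype, Mmp3 for RT, Il2rb, Cd28, Cd3e, Acta2 and Pdgfrb for the combination against isotype, Prf1, Cd28, Cd2, Havcr2, Pdcd1, Cd80, Erg and Tek for RT+1D11 against RT, Havcr2 and Tnfrsf9 for RT+1D11 against 1D11, and Nkg7, Cd28 and Havcr2 for the interaction. The probe sets of granzyme paralogs can share signal, so the levels of single members of that family are uncertain.

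Alternatives fixed beforehand were no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set, a further quantile normalization, array quality weights, a trended and robust prior, a minimum absolute log2 fold change of 1, a fit of only the 2 groups compared, the mouse number as a replicate block, averaging an effect over the other factor, the other list tests, and leaving out each array in turn. Skin and muscle scores as covariates, the estimated correlation without isotype replicate 2 and the list of sterol synthesis genes were added after seeing the data. On simulated data with 100 genes shifted by a log2 value of 1 and 100 by 2 among the 13775, the recovered percentages were 66 and 95 for 1D11 against isotype, 77 and 94 for RT against isotype, 77 and 93 for RT+1D11 against isotype, 83 and 93 for RT+1D11 against RT, 74 and 97 for RT+1D11 against 1D11, and 50 and 89 for the interaction. In the same simulations 17, 5, 8, 9, 5 and 4 other genes were called. The simulated noise was independent between genes, without an outlying array or shared skin and muscle variation. These percentages therefore do not give the recovery in the real arrays. The 12 arrays limit the precision of every value.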

Results

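Gene expression was measured on arrays in 12 flank tumours grown from 4T1 cells, a mouse mammary carcinoma line, in female Balb/C mice, with 3 tumours from separate mice in each of 4 groups. Mice received 1D11, an antibody that neutralizes every isoform of the cytokine TGF-beta, or an isotype control antibody, and tumours either stayed unirradiated or received local radiotherapy (RT). The groups are named isotype, 1D11, RT and RT+1D11. The study asked how irradiation and TGF-beta blockade, alone and together, alter gene expression in these tumours. An array gives an intensity for each probe set and no read count, so the number of arrays limits the precision. The median intensity per array lay between 61.5 and 64.8, and the log2 values of any pair of arrays correlated across probe sets, which are not independent replicates, with r between 0.915 and 0.992.

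Markers of skin and muscle differed between tumours within groups. The skin keratinocyte score, the mean log2 deviation of 13 markers from their mean over all arrays, was 2.95, 3.53 and -1.74 in the isotype tumours and 2.71, 2.27 and -2.41 in the 1D11 tumours. It was 1.67, -2.29 and -2.42 in the RT tumours and -2.29, -2.28 and 0.29 in the RT+1D11 tumours. The score of 19 skeletal muscle markers reached 3.17 in 1D11 replicate 3 and 2.92 in RT+1D11 replicate 2, against -2.27 in isotype replicate 2. Isotype replicate 2 stood apart from the other arrays, at -61.6 on a first principal component that held 39.9% of the variance, with a median correlation of 0.934 with the other arrays. It also had the largest differences between 3' and 5' control probe sets, a measure of RNA integrity, at log2 0.67 for actin and 0.39 for Gapdh, against at most 0.65 and 0.26 in the other arrays. Its array quality weight was the lowest, at 0.166.

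In unirradiated tumours, 1D11 was compared with the isotype control to ask what TGF-beta blockade alone did. No gene passed. The type I interferon-stimulated genes, which cells switch on in response to interferon, were higher with 1D11 in 29 of 29 measured members, with a median log2 fold change of 0.87 (n = 3 tumours per group). Adjusted over the list alone, 23 of the 29 passed, against 0 adjusted over all genes. Among them were Irf7, a transcription factor of the interferon response, at 1.18 (SE 0.28), Cmpk2 at 2.35 (SE 0.54) and Oasl2 at 1.61 (SE 0.38). The list was called by camera (adjusted p = 4.47e-25), with adjusted p = 0.366 with an estimated correlation. Of 23 p53 target genes, 18 were higher (median 0.21) and 4 passed adjusted over the list alone, with adjusted p = 0.366 with an estimated correlation. They included Eda2r, a receptor of the TNF receptor family, at 1.50 (SE 0.31, or 1.29 with 2 isotype values under the filter level raised to it), and Ccng1, a cyclin induced by p53, at 0.57 (SE 0.14). Of 22 hypoxia and glycolysis genes, 22 were lower (median -0.32) and 1 passed adjusted over the list alone, the glycolytic enzyme gene Pfkp at -0.51 (SE 0.11), with adjusted p = 0.366 with an estimated correlation. The 20 endothelial markers had a median of -0.43, with 19 lower and 0 passing adjusted over the list alone (camera adjusted p = 1.77e-05, and adjusted p = 0.469 with an estimated correlation). The 23 measured TGF-beta-induced genes had a median of 0.04, with 13 higher and 10 lower (camera adjusted p = 0.160, and adjusted p = 0.618 with an estimated correlation). The 19 skeletal muscle markers were higher in 19 of 19 members, with a median of 2.72 and adjusted p = 0.469 with an estimated correlation.

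Among the genes nearest to the threshold in this comparison (adjusted p = 0.696 each), Ube2q2 differed by 0.65 (SE 0.12) and Bcorl1 by 0.50 (SE 0.10). Kcne3, a potassium channel subunit gene, was lower by at least 0.78, with its 3 values with 1D11 under the filter level, while Mical1 was at -0.80 (SE 0.14) and Birc3, an inhibitor of apoptosis, at -0.51 (SE 0.10). The cyclin-dependent kinase inhibitor gene Cdkn1a was at 0.73 (SE 0.39, adjusted p = 0.775) and Itgae, which encodes the integrin CD103, at -0.91 (SE 0.36, adjusted p = 0.766). With limma, 0 of 13775 genes passed and 880 had an unadjusted p under 0.05, against 689 expected by chance. Genes are not independent, so an excess over that number is not a test. With array quality weights and with a fit of only these 2 groups, 0 passed also. The 23 interferon-stimulated genes passing adjusted over the list alone became 4 without isotype replicate 2, 0 without 1D11 replicate 1 and 0 without 1D11 replicate 2. The 4 p53 target genes became 1 without isotype replicate 3, 1D11 replicate 1 or 1D11 replicate 2. Over all genes, 2 passed without isotype replicate 2 or 1D11 replicate 3. The hypoxia count of 1 became 10 without isotype replicate 3 and 0 without isotype replicate 1 or 1D11 replicate 3, and the 0 muscle markers passing adjusted over the list alone became 8 without isotype replicate 1, 16 without RT+1D11 replicate 1 and 17 without RT+1D11 replicate 2. The endothelial score was 0.70 in isotype replicate 2 and -0.23 and -0.02 in the other isotype tumours. Without isotype replicate 2 the list medians became 0.56 for interferon-stimulated genes, -0.19 for hypoxia genes, -0.12 for endothelial markers and 0.19 for TGF-beta-induced genes, which camera then called (adjusted p = 0.000143, and adjusted p = 0.385 with an estimated correlation). The median of TGF-beta-induced genes was -0.04 without isotype replicate 3, 0.13 without 1D11 replicate 1 and 0.01 without 1D11 replicate 2, and that of muscle markers was 1.70 without 1D11 replicate 3. With skin and muscle scores as covariates, endothelial markers had a median of -0.16 and TGF-beta-induced genes one of 0.15.

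In isotype-treated mice, irradiated tumours were compared with unirradiated ones to ask what RT alone did. No gene passed. Inflammatory cytokine and chemokine genes were lower in irradiated tumours in 24 of 24 measured members (median log2 fold change -0.80, n = 3 tumours per group), and 1 passed adjusted over the list alone, Mmp3, a matrix metalloproteinase gene, at -2.10 (SE 0.37). The list was called by camera (adjusted p = 3.49e-07), with adjusted p = 0.627 with an estimated correlation. Proliferation genes were higher in 30 of 31 members, with a median of 0.21, 0 passing adjusted over the list alone and adjusted p = 0.627 with an estimated correlation. Collagen and extracellular matrix genes had a median of -0.33, with 25 of 32 lower, 0 passing adjusted over the list alone and adjusted p = 0.627 with an estimated correlation. Skin keratinocyte markers had a median of -2.73, with 13 of 13 lower and adjusted p = 0.627 with an estimated correlation. Skeletal muscle markers were higher in 19 of 19 (median 1.55, 0 passing adjusted over the list alone), with adjusted p = 0.648 with an estimated correlation. Camera also called neutrophil markers (median -0.80, 17 of 19 lower) and immediate early and heat shock genes, which respond to tissue handling (median -0.53, 12 of 14 lower). In each of these 2 lists 0 passed adjusted over the list alone, with adjusted p = 0.627 with an estimated correlation. Isotype replicate 2 had the highest score of all arrays for the inflammatory, neutrophil and immediate early lists, at 1.20, 1.57 and 0.71. Without it the medians became -0.38, -0.16 and -0.17 for these lists, 0.09 for proliferation genes, -0.03 for collagen and matrix genes and -1.57 for skin markers. With skin and muscle scores as covariates the medians were -0.22 for inflammatory genes, -0.11 for neutrophil markers, -0.20 for immediate early genes and -0.18 for collagen and matrix genes.

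The genes nearest to the threshold for RT alone (adjusted p = 0.274 each) were Syde1 at 0.80 (SE 0.12), Klhl23 at 0.87 (SE 0.14) and Tead2, a transcription factor of the Hippo pathway, at 0.84 (SE 0.14) in the higher direction. In the lower direction they were Cxcl13, a chemokine that attracts B cells, at -2.10 (SE 0.32), Birc3 at -0.59 (SE 0.10) and Mmrn1, which was lower by at least 0.23, with its 3 RT values under the filter level. Cxcl16, a chemokine for T cells that carry CXCR6, was at -0.59 (SE 0.21, adjusted p = 0.347), Tgfb3 at 0.63 (SE 0.19, adjusted p = 0.326) and Ccn2, a gene induced by TGF-beta, at -1.24 (SE 0.57, adjusted p = 0.381). With limma, 0 genes passed, 1821 had an unadjusted p under 0.05 (689 expected by chance), and 0 passed with array quality weights or with a fit of only these 2 groups. Without isotype replicate 3, 57 genes passed, and the inflammatory count of 1 became 2 without 1D11 replicate 3 or RT+1D11 replicate 3. The collagen and matrix genes passing went from 0 to 1 lower gene without isotype replicate 1 (median -0.55) and 1 higher gene without isotype replicate 2, and their median was -0.52 without RT replicate 1 and -0.19 without RT replicate 2. The immediate early genes passing went from 0 to 1 lower gene without isotype replicate 1 or isotype replicate 3 and 1 higher gene without isotype replicate 2. Without RT replicate 2 the median was -0.52 for neutrophil markers and -1.67 for skin markers, and without isotype replicate 3 it was -4.27 for skin markers.

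The combined treatment was compared with isotype alone to ask what both treatments did together, and 23 genes passed, 17 higher and 6 lower. Klrg1, a receptor on effector T and natural killer cells, rose from a log2 level of 6.67 ± 0.07 to 8.94 ± 0.12 (SD, n = 3), which is 4.84-fold (95% interval 3.84 to 6.11, adjusted p = 0.000242). Gzmb, the serine protease granzyme B, rose 8.50-fold, with a log2 fold change of 3.09 (SE 0.43, adjusted p = 0.0283). Prf1, the pore-forming protein perforin, rose by 2.98 (SE 0.36, adjusted p = 0.0188), and by 1.54 to 3.26 under the alternatives. The granzyme gene Gzmc rose by 2.78 (SE 0.36). The granzyme genes Gzmg and Gzmf also rose (adjusted p = 0.0297 each), by 6.56 and 5.78 with isotype values under the filter level raised to it (2 of Gzmg and 1 of Gzmf). The isotype values spanned 4.14 to 8.76 for Gzmg and 5.23 to 8.36 for Gzmf, so the sizes of these rises are uncertain. Ctsg, the neutrophil and mast cell protease cathepsin G, rose by 3.34 (SE 0.41), and Tmsb15a rose by 3.06 (SE 0.47). Further rises were those of the granzyme inhibitor family member Serpinb9b by 2.08 (SE 0.29), Atp8b4 by 1.86 (SE 0.29, and 0.99 to 2.21 under the alternatives) and Irf7 by 1.80 (SE 0.28, adjusted p = 0.0418). Cyp51 and Pmvk, both enzymes of cholesterol synthesis, fell by 2.29 (SE 0.32) and 0.99 (SE 0.16). Kcne3, with its 3 RT+1D11 values under the filter level, fell by at least 0.78. Further, the RNA polymerase III subunit gene Polr3g fell by 0.95 (SE 0.11), Tlcd1 fell by 0.80 (SE 0.12) and Slc36a4 fell by 0.66 (SE 0.10). Under the alternatives the log2 fold change of Tlcd1 ran from -0.86 to -0.23. The T cell coreceptor gene Cd8a, at 1.13 (SE 0.27, adjusted p = 0.163), Itgae, at -1.23 (SE 0.36, adjusted p = 0.288), and the interferon-induced chemokine gene Cxcl10, at 1.44 (SE 0.67, adjusted p = 0.532), were not called.

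**Figure D1:**
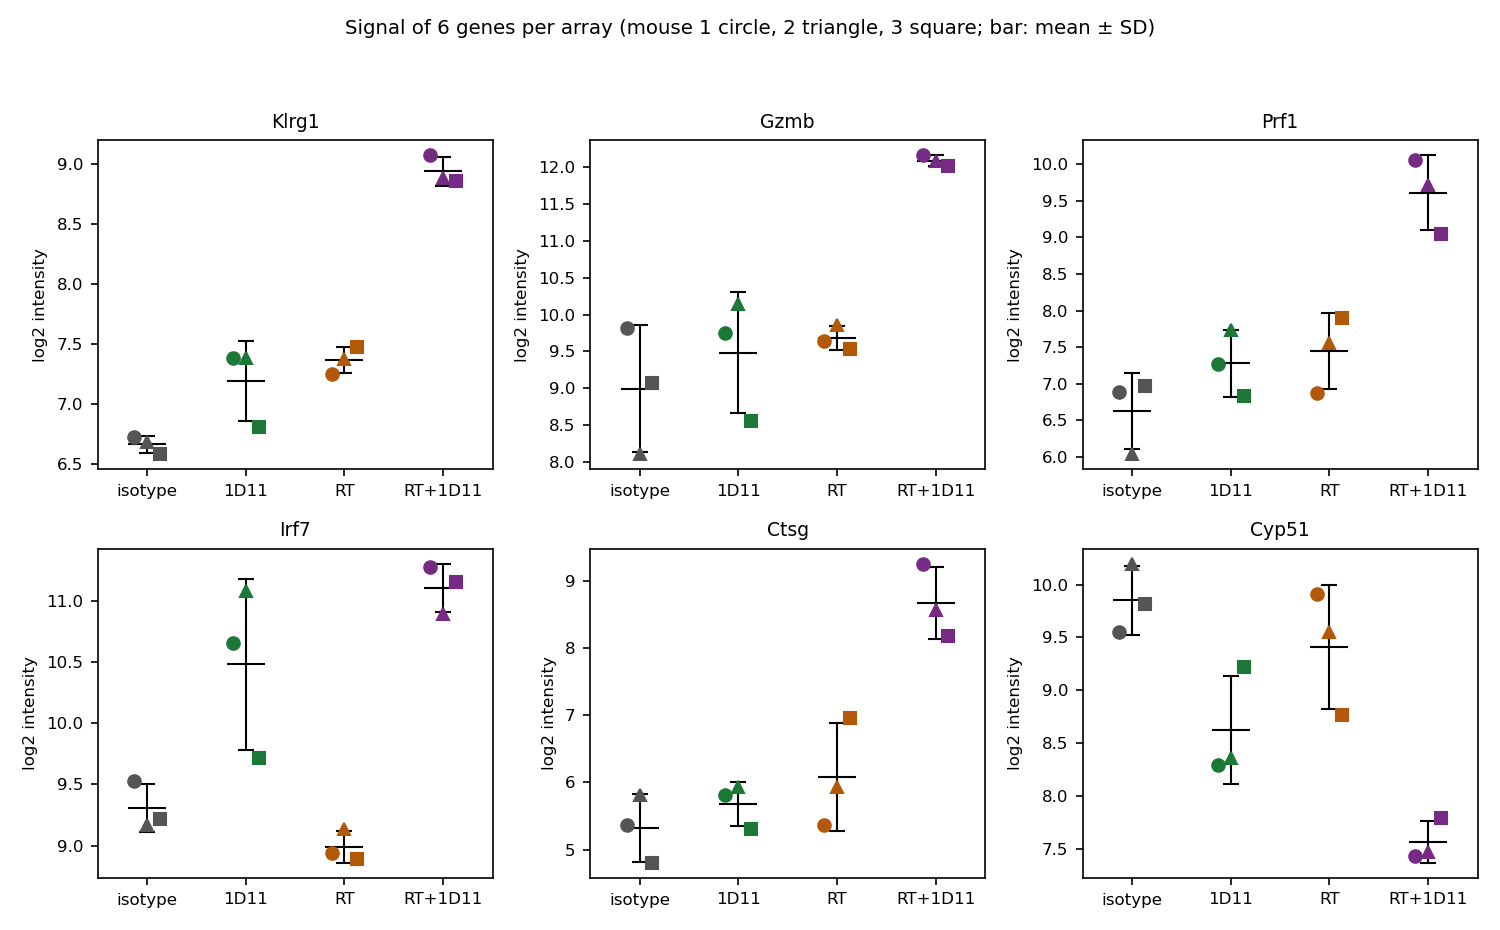
Log2 intensity of 6 genes in each of the 12 tumours, by group on the horizontal axis, with the mouse number as the symbol and bars for the mean and SD of 3 arrays. Klrg1 lay at 8.94 on average in RT+1D11 tumours and at 6.67 in isotype tumours, and the group mean of Cyp51 was 7.57 against 9.85.

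Of 17 measured cytotoxic and natural killer genes, 16 were higher with the combination (median 1.56), with 2 passing adjusted over all genes and 12 adjusted over the list alone. Among the 12 was Il2rb, an interleukin 2 receptor subunit, at 1.71 (SE 0.33). Of 18 T cell markers, 15 were higher (median 0.80) and 10 passed adjusted over the list alone, against 0 over all genes. They included the costimulatory receptor gene Cd28 at 1.01 (SE 0.25) and Cd3e, a T cell receptor subunit, at 0.70 (SE 0.20). All 29 interferon-stimulated genes were higher (median 1.25), with 1 passing over all genes and 28 adjusted over the list alone. These 3 lists were called by camera, each with adjusted p = 0.333 with an estimated correlation. Fibroblast and pericyte markers were lower in 15 of 16 members (median -0.96), with 4 passing adjusted over the list alone. These included the smooth muscle actin gene Acta2 at -1.49 (SE 0.47) and the growth factor receptor gene Pdgfrb at -0.78 (SE 0.22). Collagen and extracellular matrix genes were lower in 30 of 32 (median -0.47), with 1 passing. The fibroblast and collagen lists had adjusted p = 0.515 with an estimated correlation, and skin keratinocyte markers, at a median of -3.15 with 13 of 13 lower, had the same value of adjusted p = 0.515 with an estimated correlation. Adipocyte markers were lower in 8 of 8 members (median -0.96, 0 passing adjusted over the list alone), again with adjusted p = 0.515 with an estimated correlation. Skeletal muscle markers were higher in 19 of 19 (median 1.69, 0 passing adjusted over the list alone), with adjusted p = 0.548 with an estimated correlation, and their median was 0.41 without RT+1D11 replicate 2 and 2.79 without RT+1D11 replicate 1. Without isotype replicate 2 the medians became 0.83 for cytotoxic genes, with 1 member passing as lower, -0.52 for fibroblast markers, -0.17 for collagen and matrix genes, -0.49 for adipocyte markers and -2.00 for skin markers. The adipocyte median was -0.39 without RT+1D11 replicate 1. With skin and muscle scores as covariates the cytotoxic median was 1.00 with 7 passing adjusted over the list alone, 0 T cell markers and 1 fibroblast marker passed, and the adipocyte median was -0.61. The 23 genes became 99 without isotype replicate 1, 11 without isotype replicate 2, 102 without isotype replicate 3, 7 without 1D11 replicate 1, 46 without 1D11 replicate 3, 6 without RT replicate 2, and 3, 2 and 1 without RT+1D11 replicates 1, 2 and 3. With array quality weights 2 passed, and likewise 2 with a fit of only these 2 groups, and 15 with a trended, robust prior. Adjusted over the list alone, the 10 T cell markers became 0 without RT+1D11 replicate 1 or 2, 3 without isotype replicate 2, 1 without isotype replicate 3, and 5, 6 and 5 without RT replicates 1, 2 and 3. The 4 fibroblast markers became 10 without isotype replicate 1, 2 without RT replicate 2 and 0 without isotype replicate 2, isotype replicate 3, 1D11 replicate 1, RT+1D11 replicate 2 or RT+1D11 replicate 3. The collagen count of 1 became 3 without isotype replicate 1 and 0 without isotype replicate 2, isotype replicate 3, RT+1D11 replicate 1 or RT+1D11 replicate 2, and without isotype replicate 3 the 0 skin markers passing became 11 (median -4.76) and the 0 adipocyte markers became 2.

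Within irradiated tumours, RT+1D11 was compared with RT to ask what TGF-beta blockade added to irradiation, and 20 genes passed, 16 higher and 4 lower. Klrg1 rose by 1.57 (SE 0.15, adjusted p = 0.00592) and Plac8 by 2.13 (SE 0.21, adjusted p = 0.00592), from a log2 level of 10.03 ± 0.18 to 12.16 ± 0.30 (SD, n = 3). Irf7 rose by 2.12 (SE 0.28, adjusted p = 0.0206), Ifit1bl1 by 2.21 (SE 0.34) and the antiviral enzyme gene Oas1a by 1.40 (SE 0.21, adjusted p = 0.0396). Ctsg rose by 2.58 (SE 0.41), Gzmc by 2.34 (SE 0.36) and Atp8b4 by 2.01 (SE 0.29, and 1.21 to 2.24 under the alternatives). Also higher were Serpinb9b by 1.92 (SE 0.29), Ms4a4c by 1.88 (SE 0.29) and complement factor B, Cfb, by 1.57 (SE 0.21). Acss2, an acetyl-CoA synthetase gene, fell by 1.02 (SE 0.13), Klhl23 fell by 0.91 (SE 0.14), Polr3g fell by 0.82 (SE 0.11) and Sgtb fell by 0.77 (SE 0.12). Under the alternatives the log2 fold change of Acss2 ran from -1.06 to -0.60. Not called were Gzmb at 2.41 (SE 0.43, adjusted p = 0.0642), Prf1 at 2.17 (SE 0.36, adjusted p = 0.0548), and Cd8a at 1.20 (SE 0.27, adjusted p = 0.117). Neither were Ifng, the cytokine interferon gamma, at 1.33 (SE 0.43, adjusted p = 0.268), Cd274, the checkpoint ligand PD-L1, at 1.19 (SE 0.36, adjusted p = 0.230), and Cdkn1a at 1.20 (SE 0.39, adjusted p = 0.265).

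All 29 interferon-stimulated genes were higher in RT+1D11 than in RT tumours (median 1.40), with 2 passing over all genes and 29 adjusted over the list alone. All 17 cytotoxic and natural killer genes were higher (median 1.46), with 0 over all genes and 15 adjusted over the list alone. Of 18 T cell markers, 17 were higher (median 1.07) and 13 passed adjusted over the list alone, including Cd28 at 1.28 (SE 0.25) and the adhesion receptor gene Cd2 at 1.20 (SE 0.29). These 3 lists were called by camera and by fry (adjusted p = 0.0253 each by fry), with adjusted p = 0.141 with an estimated correlation. Of 17 immune checkpoint and costimulation genes, 13 were higher (median 0.48), and adjusted over the list alone 5 passed as higher and 1 as lower, with adjusted p = 0.141 with an estimated correlation. The higher ones included Havcr2, the checkpoint receptor TIM-3, at 1.58 (SE 0.27), Pdcd1, the receptor PD-1, at 1.46 (SE 0.47), and the costimulatory ligand gene Cd80 at 1.22 (SE 0.29). Endothelial markers were lower in 16 of 20 (median -0.39), with 3 passing adjusted over the list alone and adjusted p = 0.701 with an estimated correlation. Among the 3 were the endothelial transcription factor gene Erg at -0.95 (SE 0.21) and the angiopoietin receptor gene Tek at -1.31 (SE 0.34). TGF-beta-induced genes had a median of 0.03 (camera adjusted p = 0.836), and skin keratinocyte markers a median of -0.35 (camera adjusted p = 0.836). Camera called 14 lists in this comparison, 12 as higher and 2 as lower. Average scores in RT+1D11 and RT tumours were 0.17 and -0.46 for inflammatory genes. They were 0.16 and -0.11 for macrophage markers and 0.05 and -0.24 for immediate early genes.

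The 20 genes called between RT+1D11 and RT became 134 without isotype replicate 2, 39 without isotype replicate 1, 46 without 1D11 replicate 3, 2 without 1D11 replicate 1, 11 without 1D11 replicate 2, 1, 0 and 0 without RT replicates 1, 2 and 3, and 3, 2 and 4 without RT+1D11 replicates 1, 2 and 3. With array quality weights 841 genes passed, and 158 with a fit of only these 2 groups. The smallest list-alone count without any 1 array was 27 for interferon-stimulated genes and 13 for cytotoxic genes, while the 13 T cell markers became 6 without RT replicate 2 or RT+1D11 replicate 2. With 1 array left out, the adjusted p by fry reached 0.102 for interferon-stimulated genes, 0.104 for cytotoxic genes and 0.102 for T cell markers. Each of these 3 fry calls was thus lost without some array. Klrg1 had adjusted p = 0.0523, 0.0643 and 0.0505 without RT replicates 1, 2 and 3. The 5 higher checkpoint genes became 8 without isotype replicate 3, 2, 1 and 3 without RT replicates 1, 2 and 3, and 3, 2 and 3 without RT+1D11 replicates 1, 2 and 3, and the 3 endothelial markers became 1 without RT replicate 1 and 0 without RT replicate 3 or RT+1D11 replicate 3. The median of TGF-beta-induced genes was -0.14 without RT replicate 1, -0.0054 without RT replicate 2, and -0.07, -0.13 and 0.06 without RT+1D11 replicates 1, 2 and 3, and 0.01 with skin and muscle scores as covariates.

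**Figure D2:**
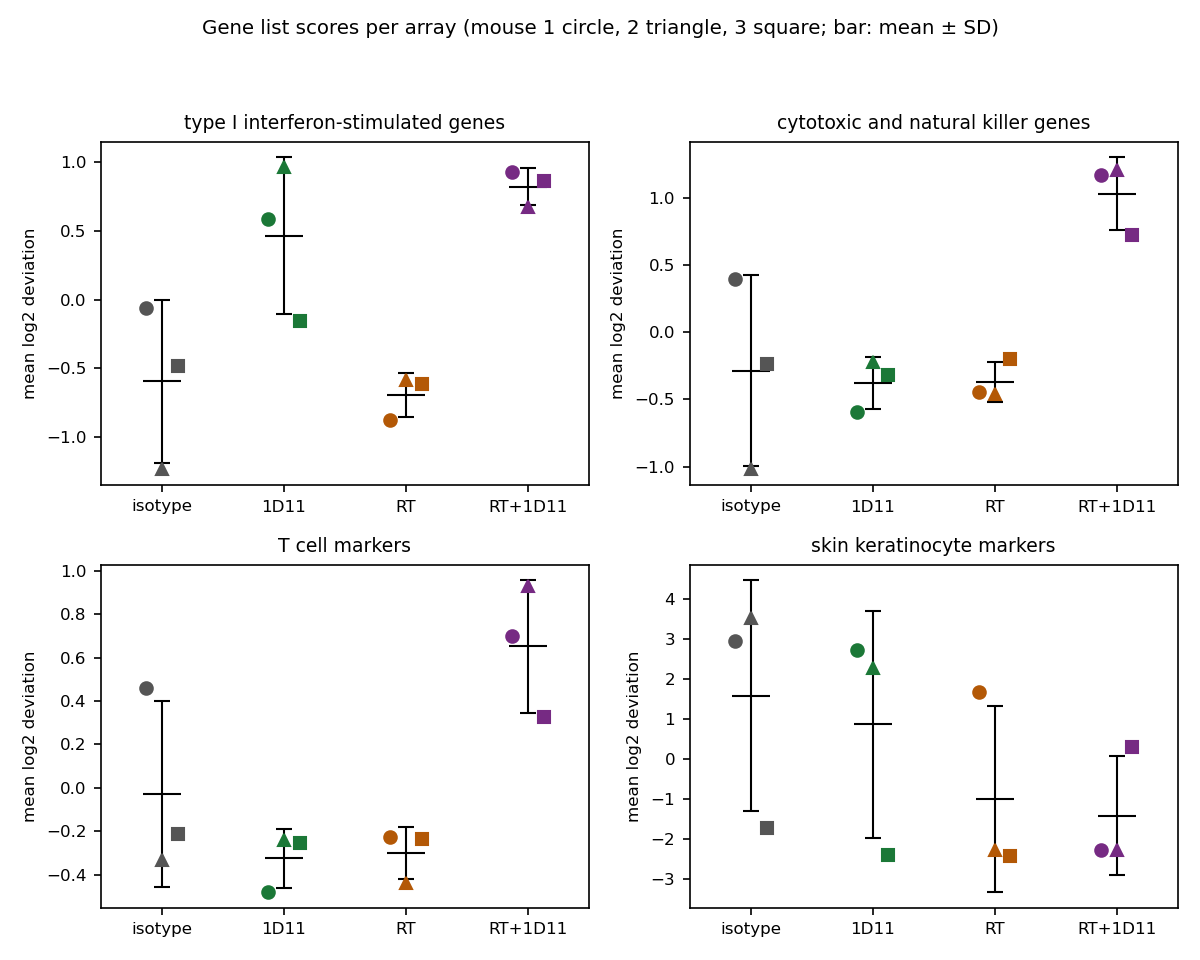
Mean log2 deviation of 4 gene lists from their mean over all arrays, in each of the 12 tumours, by group, with the mouse number as the symbol and bars for the mean and SD of 3 arrays. The cytotoxic score averaged 1.03 in RT+1D11 tumours and lay between -0.38 and -0.29 in the other groups, while the skin score spread over several log2 units within groups.

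In mice given 1D11, irradiated tumours were compared with unirradiated ones to ask what RT added to TGF-beta blockade, and 2 genes passed. Klrg1 rose by 1.75 (SE 0.15, adjusted p = 0.00339), which is 3.36-fold, and Sh2d2a, an adaptor of T cell signalling, rose by 0.89 (SE 0.11, adjusted p = 0.0372), from a log2 level of 6.93 ± 0.14 to 7.82 ± 0.09 (SD, n = 3). Not called were Gzmb at 2.60 (SE 0.43, adjusted p = 0.111), Cd8a at 1.40 (SE 0.27, adjusted p = 0.165), Ifng at 1.21 (SE 0.43, adjusted p = 0.756) and Ccn2 at -1.60 (SE 0.57, adjusted p = 0.756). Cytotoxic and natural killer genes were higher in 16 of 17 members (median 1.54), with 0 passing over all genes and 14 adjusted over the list alone, and T cell markers in 14 of 18 (median 1.03), with 12 adjusted over the list alone. Both lists were called by camera and by fry (adjusted p = 0.0477 and 0.0353 by fry), with adjusted p = 0.0712 with an estimated correlation. Of 17 checkpoint and costimulation genes, 14 were higher (median 0.53) and 5 passed adjusted over the list alone, with adjusted p = 0.0712 with an estimated correlation. They included Havcr2 at 1.18 (SE 0.27) and the costimulatory receptor gene Tnfrsf9 at 1.17 (SE 0.29). Collagen and extracellular matrix genes were lower in 30 of 32 (median -0.48, 1 passing adjusted over the list alone) and epithelial markers in 17 of 19 (median -0.21, 0 passing), and each list had adjusted p = 0.312 with an estimated correlation. Skin keratinocyte markers were lower in 13 of 13 (median -2.38), with adjusted p = 0.492 with an estimated correlation. Fibroblast and pericyte markers were lower in 14 of 16 (median -0.80, 1 passing adjusted over the list alone), with adjusted p = 0.372 with an estimated correlation. Adipocyte markers were lower in 7 of 8 (median -0.92, 0 passing) and skeletal muscle markers in 19 of 19 (median -1.04, 0 passing), with adjusted p = 0.312 and 0.673 with an estimated correlation. The score of TGF-beta-induced genes averaged 0.13 in 1D11 and -0.12 in RT+1D11 tumours. For RT averaged over both antibody arms, 16 of these 23 genes were lower (median -0.12, camera adjusted p = 0.00275, and adjusted p = 0.416 with an estimated correlation).

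The 2 genes called between RT+1D11 and 1D11 became 14 without isotype replicate 2, 9 without isotype replicate 1, 3 without isotype replicate 3, and 1 without 1D11 replicate 1, 1D11 replicate 2, RT replicate 1, RT replicate 2 or any of the RT+1D11 replicates. Klrg1 had adjusted p = 0.0952 in a fit of only these 2 groups, while Sh2d2a had adjusted p between 0.0532 and 0.187 without any 1 array of the 1D11, RT or RT+1D11 groups. With 1 array left out, the adjusted p by fry reached 0.198 for cytotoxic genes and 0.158 for T cell markers, so both fry calls were lost without some array. The 5 checkpoint genes became 2, 9 and 1 without 1D11 replicates 1, 2 and 3 and 2 without RT+1D11 replicate 2. The collagen count of 1 became 5 without isotype replicate 2, 2 without RT+1D11 replicate 2 and 0 without 1D11 replicate 1, 1D11 replicate 3 or RT+1D11 replicate 1. The epithelial median was -0.10 without RT+1D11 replicate 1, and the skin median -1.54 without 1D11 replicate 1 and -4.17 without 1D11 replicate 3. With skin and muscle scores as covariates the medians were -0.05 for epithelial markers and -0.32 for collagen and matrix genes, and 0 fibroblast markers passed. The muscle median was -0.03 without 1D11 replicate 3, 0.07 without RT+1D11 replicate 1 and -2.32 without RT+1D11 replicate 2, and the fibroblast median was -0.42 without 1D11 replicate 3. The fibroblast count of 1 became 6 without isotype replicate 2 and 0 without 1D11 replicate 1 or any of the RT+1D11 replicates, and the adipocyte count of 0 became 3 without isotype replicate 2 and 1 without RT replicate 3 or RT+1D11 replicate 2.

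The interaction asked whether the change with 1D11 differed between irradiated and unirradiated tumours. No gene passed. For cytotoxic and natural killer genes the change with 1D11 was more positive in irradiated tumours in 17 of 17 members (median log2 interaction 1.71), with 12 passing adjusted over the list alone. Among them were Ctsw, a protease of cytotoxic lymphocytes, at 1.63 (SE 0.28), Nkg7 at 2.16 (SE 0.63) and Gzmb at 1.92 (SE 0.61). T cell markers had a median of 1.47, with 17 of 18 in that direction and 11 passing adjusted over the list alone, including Cd28 at 1.55 (SE 0.36) and Cd8a at 1.48 (SE 0.38). Checkpoint and costimulation genes had a median of 0.85, with 5 passing adjusted over the list alone, including Havcr2 at 1.75 (SE 0.39). By camera the 3 lists were called, with adjusted p = 0.190, 0.171 and 0.171 with an estimated correlation. Inflammatory cytokine and chemokine genes had a median of 1.11 with 23 of 24 in that direction and 0 passing adjusted over the list alone, and adjusted p = 0.301 with an estimated correlation. Skeletal muscle markers had a median of -2.26 in 19 of 19 members, with adjusted p = 0.618 with an estimated correlation.

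The genes nearest to the threshold for the interaction (adjusted p = 0.330 each) were Hcst, a signalling adaptor of lymphocyte receptors, at 1.05 (SE 0.16), Ctsw, Sh2d2a at 0.86 (SE 0.15), Klhl23 at -1.14 (SE 0.19), Gas2 at -1.25 (SE 0.22) and Spin4 at -0.94 (SE 0.17). With limma, 0 genes passed, 1344 had an unadjusted p under 0.05 (689 expected by chance), and 0 passed with array quality weights and with a trended, robust prior. Without isotype replicate 2, 2 genes passed. The 12 cytotoxic genes became 1 without isotype replicate 1, isotype replicate 3, 1D11 replicate 1, RT replicate 1, RT replicate 2, RT+1D11 replicate 1 or RT+1D11 replicate 2. The 11 T cell markers became 7 without RT+1D11 replicate 2. The 5 checkpoint genes became 1 without isotype replicate 1, 1D11 replicate 1 or RT replicate 1, 2 without RT replicate 2, 3 without RT+1D11 replicate 1 and 9 without isotype replicate 2. Without RT+1D11 replicate 2, the 0 muscle markers passing adjusted over the list alone became 17 (median -3.64) and the 0 inflammatory genes became 1. The muscle median was -1.36 without 1D11 replicate 3 and -1.33 without RT+1D11 replicate 1.

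Across the genes tested, which are not independent replicates, the log2 fold changes of RT without and with 1D11, taken from separate arrays, correlated with r = 0.32, and those of 1D11 without and with RT with r = 0.15. Spearman's rho was -0.08 and -0.06, and 46.3% and 45.6% of all genes had the same sign, so the positive r was carried by part of the genes. Without RT+1D11 replicate 2 the r of the 1D11 effects was -0.03. Of the 20 genes called between RT+1D11 and RT, 17 had the same sign between 1D11 and isotype. At an unadjusted p under 0.001, 114 genes differed between RT+1D11 and RT, and 87 of them had the same sign between 1D11 and isotype. At that threshold 13 genes differed between 1D11 and isotype, and 6 of them had the same sign between RT+1D11 and RT. Camera called 20 lists for 1D11 against isotype, 19 for RT against isotype and 14 for RT+1D11 against isotype. It called 14 for RT+1D11 against RT, 17 for RT+1D11 against 1D11 and 16 for the interaction. With an estimated correlation 0 of these held in each comparison, and fry called 3 for RT+1D11 against RT, 2 for RT+1D11 against 1D11 and 0 in the rest of these comparisons. Of the 20 genes chosen beforehand as a panel, 18 were tested, and of these Gzmb passed between RT+1D11 and isotype while 0 passed in each other comparison.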

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

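Among the tests in this part, the comparison of cytotoxic with pan T cell genes, the test without granzymes, the test without isotype replicate 2, the test against macrophage markers, the splits behind the correlations and the fits with skin and muscle scores were chosen only after the result was seen, and the splits of gene and list counts were not.

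The change with 1D11 differed between irradiated and unirradiated tumours for 16 lists by camera's test of the interaction at its preset correlation, and for 0 with an estimated correlation or with fry. The median log2 interactions were 1.71 for cytotoxic and natural killer genes, 1.47 for T cell markers, 1.11 for inflammatory cytokines and chemokines, 0.93 for neutrophil markers, 0.85 for checkpoint and costimulation genes, 0.53 for regulatory T cell markers, 0.50 for immediate early and heat shock genes, 0.47 for monocyte and macrophage markers, 0.45 for type I interferon-stimulated genes, 0.42 for B and plasma cell markers, 0.42 for hypoxia and glycolysis genes and 0.21 for interferon-gamma and antigen presentation genes. They were -2.26 for skeletal muscle markers, -0.29 for DNA repair genes, -0.28 for proliferation genes and -0.27 for epithelial markers. Without isotype replicate 2 the medians became 0.77 for type I interferon-stimulated genes, 0.70 for interferon-gamma genes, 0.82 for macrophage markers, 0.36 for neutrophil markers, 0.34 for regulatory T cell markers, 0.24 for hypoxia genes, 0.11 for immediate early genes, -0.17 for proliferation genes and -0.07 for DNA repair genes. Without isotype replicate 1 they were -0.04 for interferon-gamma genes, which turned, 0.22 for type I interferon-stimulated genes and 0.24 for macrophage markers. Without isotype replicate 3 they were 0.02 for interferon-gamma genes, 0.28 for macrophage markers, -0.47 for DNA repair genes and -0.12 for epithelial markers. The interferon-gamma median was also 0.11 without 1D11 replicate 1, 0.36 without 1D11 replicate 2 and 0.14 without RT replicate 3, and the type I interferon median 0.70 without 1D11 replicate 2 and 0.20 without 1D11 replicate 3. Without 1D11 replicate 3 the neutrophil median was 0.62 and the muscle median -1.36, and without RT replicate 3 the regulatory T cell median was 0.34. Without RT+1D11 replicate 1 the medians were 0.51 for neutrophil markers, -0.18 for proliferation genes and -1.33 for muscle markers, without RT+1D11 replicate 2 -3.64 for muscle markers, and without RT+1D11 replicate 3 -0.43 for proliferation genes and -0.40 for epithelial markers. With skin and muscle scores as covariates they were 0.23 for neutrophil markers, 0.26 for immediate early genes and 0.33 for interferon-gamma genes. In 100 assignments of the 12 arrays to 4 groups, the real one included, 26 gave as many lists and the highest of the others was 21. These assignments also mix any RT and 1D11 effects into the contrast. They therefore do not measure chance for the interaction alone, and chance is not excluded. The interaction called 0 genes and the highest of the other assignments was 2. That 100 of the 100 assignments gave as many was fixed in advance, as no count lies under 0. Among probe sets with no single gene, which the comparisons of genes do not use, 1 was called, as higher in RT+1D11 than in RT.

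Cytotoxic genes were higher in RT+1D11 than in RT tumours by a mean of 1.40 (SE 0.326). The 14 members that are not granzymes still shifted by 1.24 (SE 0.332), which argues against signal shared by granzyme paralogs as the whole source, and with skin and muscle scores as covariates the shift was 1.36 (SE 0.339), which argues against those tissues. The list exceeded 7 pan T cell genes, which shifted by 1.04 (SE 0.258), by 0.358 (SE 0.203), less than 2 SE, so the values are consistent with more T cells at unchanged expression per cell, and more expression per cell stays open too. A change in lymphocyte content or state with the combined treatment, which the design names, remains a hypothesis that these bulk tumours did not test.

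Interferon-stimulated genes were higher with 1D11. Without isotype replicate 2 the mean shift of the list between 1D11 and isotype was 0.740 (SE 0.315), against 1.06 (SE 0.348) with it. The first value lies above 0 by little more than 2 SE, a bound chosen after the result was seen. The scores also overlapped, at -0.16 in 1D11 replicate 3 and -0.06 in isotype replicate 1. Between 1D11 and isotype, isotype replicate 2 as the only source is therefore not excluded. Adjusted over the list alone, 0 members passed without 1D11 replicate 1 or 2, but those fits keep isotype replicate 2 and do not bear on it. The means of RT+1D11 and RT tumours hold no isotype array, so that array is not the source of a difference between them. Between RT+1D11 and RT the mean shift was 1.52 (SE 0.348), and 1.54 (SE 0.388) with skin and muscle scores as covariates, which argues against those tissues in irradiated tumours. The same score test was not made between 1D11 and isotype. The shift between RT+1D11 and RT exceeded that of monocyte and macrophage markers, 0.264 (SE 0.211), by 1.25 (SE 0.288), which argues against more of these leukocytes alone, while an effect of 1D11 itself stays open.

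The 6 tumours of each pair of groups make 10 splits, too few for a share under 0.05. The real split called 23 genes between RT+1D11 and isotype and the highest of the others 0, with 1 of 10 splits as large. For RT+1D11 against RT the values were 20 and 0 (1 of 10), for RT+1D11 against 1D11 2 and 0 (1 of 10), for 1D11 against isotype 0 and 1 (10 of 10) and for RT against isotype 0 and 10 (10 of 10). The shares of 10 of 10 were fixed in advance, as no split can call fewer than 0 genes. The other split with 10 genes, against 0 in the real one, may reflect a structure of these 6 tumours or chance, and which of these holds was not tested. For lists, the real split and the highest other gave 20 and 21 (2 of 10 as large) for 1D11 against isotype, 19 and 18 (1 of 10) for RT against isotype, 14 and 19 (6 of 10) for RT+1D11 against isotype, 14 and 19 (3 of 10) for RT+1D11 against RT, and 17 and 15 (1 of 10) for RT+1D11 against 1D11. For the correlation of the RT effects, r = 0.32, 11 of 100 assignments within the arms gave one as large and the highest other was 0.661, and for that of the 1D11 effects, r = 0.15, the values were 28 of 100 and 0.643, so chance is excluded for neither.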

How the results depend on the processing

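All alternatives here were planned except the covariate fit and the estimated correlation without isotype replicate 2, which were chosen after seeing the data, and the cause was not tested unless stated. The 34 calls of named genes had 780 values under alternatives, of which 471 stayed past the threshold, 309 did not and 0 changed sign. The last count was largely fixed in advance. Most of these genes were named only where the groups did not overlap, and many alternatives leave the estimate as it was. Over every gene the naming rule gives, including panel genes left out of the text, 125 uncalled values had 2887 alternatives, and 105 of these, in 40 gene and comparison pairs, changed sign. Over all lists, 7 of 1600 alternative values of called lists and 86 of 992 of uncalled ones changed sign.

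Between RT+1D11 and isotype, 23 genes became 2 with a fit of only these 2 groups, 2 with array quality weights, 15 with a trended, robust prior and 15 with a log2 fold change of at least 1. Between RT+1D11 and RT, 20 became 158 with only these 2 groups, 841 with array quality weights, 31 with a further quantile normalization and 31 with a trended, robust prior. Between RT+1D11 and 1D11, 2 became 0 with only these 2 groups, 1 with every probe set, 90 with array quality weights, 1 with a trended, robust prior and 1 with a log2 fold change of at least 1. Averaging over the other factor, which sets 6 arrays against 6, took the 0 genes for 1D11 to 23 and the 0 for RT to 2. With skin and muscle scores as covariates the counts were 0, 0, 17, 21, 2 and 0, in the order 1D11 against isotype, RT against isotype, RT+1D11 against isotype, RT and 1D11, and interaction.

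With the mouse number as a replicate block, the counts between RT+1D11 and isotype, RT and 1D11 were 1, 2 and 1, and 0 in the other comparisons. The numbers do not pair the tumours: 18 pairs sharing a number had correlations of deviations from -0.60 to 0.49 (median -0.08), 5 were over 0.1, and 3 of 12 arrays correlated best with their own number.

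With an estimated correlation, camera's lists of 20, 19, 14, 14, 17 and 16 became 0 in each comparison, and with fry 0, 0, 0, 3, 2 and 0. Each of these fry calls was lost when some 1 array was left out. For 1D11 against isotype without isotype replicate 2 the estimated correlation also left 0.

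Leaving out 1 array gave 0 to 2 genes for 1D11 against isotype, 0 to 57 for RT against isotype, 1 to 102 for RT+1D11 against isotype, 0 to 134 for RT+1D11 against RT, 1 to 14 for RT+1D11 against 1D11 and 0 to 2 for the interaction. Lists ranged from 12 to 21, 11 to 19, 10 to 20, 12 to 15, 11 to 18 and 14 to 20. The correlation of RT effects ranged from 0.115 to 0.499. That of 1D11 effects ranged from -0.0257, without RT+1D11 replicate 2, to 0.241. The median of TGF-beta-induced genes between RT+1D11 and RT ranged from -0.138 to 0.0621 and was 0.0301 without isotype replicate 2, 0.0323 without RT replicate 3 and 0.0621 without RT+1D11 replicate 3, where camera's direction turned. The median of skeletal muscle markers between RT+1D11 and 1D11 ranged from -2.32, without RT+1D11 replicate 2, to 0.0678, without RT+1D11 replicate 1, where the direction turned. Low signal over background limits genes near the filter.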

Other observations

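The tests on sterol synthesis genes use a list chosen only after the called genes were seen, the fit with skin and muscle scores was also chosen after the data were seen, and the reading of sebaceous, melanocyte and other hair follicle values was made after the result of the hair follicle test was seen.

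Averaged over both RT arms, 1D11 changed 23 genes, 13 higher and 10 lower. The higher ones included Klrg1 at 1.05 (SE 0.11, adjusted p = 0.0124), Plac8 at 1.40 (SE 0.15), Irf7 at 1.65 (SE 0.20) and Ifit3 at 2.35 (SE 0.37). All 29 type I interferon-stimulated genes were higher (median 1.09), with 3 passing over all genes and 29 adjusted over the list alone. This list had adjusted p = 0.0102 by fry and 0.102 with an estimated correlation, and leaving out arrays was not tried here. Several of the lower genes belong to cholesterol synthesis. Cyp51 fell by 1.54 (SE 0.22, adjusted p = 0.0420), Insig1, a regulator of sterol sensing, fell by 1.23 (SE 0.19, adjusted p = 0.0454), Lss fell by 0.78 (SE 0.12) and Srebf2, the transcription factor that drives the pathway, fell by 0.77 (SE 0.12). Of 21 sterol synthesis genes, listed after these were seen, so not independent evidence of the direction, 21 were lower (median -0.82), with 7 passing over all genes and 20 adjusted over the list alone, and adjusted p = 0.0865 with an estimated correlation. By fry this list had adjusted p = 0.00424, with the same limit that it was chosen from these data. The 21 genes had a median of -0.78 between 1D11 and isotype, -0.89 between RT+1D11 and RT and -1.07 between RT+1D11 and isotype. By fry they had adjusted p = 0.111, 0.0165 and 0.00594 in that order. They were also lower with RT, by less, in 21 of 21 members between RT+1D11 and 1D11 (median -0.34, adjusted p = 0.287 with an estimated correlation) and in 21 of 21 averaged over both antibody arms (median -0.25, adjusted p = 0.416 with an estimated correlation). Between RT and isotype, 18 were lower and 3 higher (median -0.18, adjusted p = 0.614 with an estimated correlation). In each of these 0 passed adjusted over the list alone, and the fall was not shown to go with 1D11 alone. Averaged over both antibody arms, 2 genes passed for RT, Klrg1, which rose by 1.23 (SE 0.11, adjusted p = 0.00369), and Mab21l4, which fell by 1.66 (SE 0.20, adjusted p = 0.0463). Klrg1 rose by 1.75 with 1D11, while without it the values were 6.58 to 6.73 in isotype and 7.26 to 7.48 in RT tumours. Skin keratinocyte markers were lower in 13 of 13 members in the averaged contrast (median -2.49). Whether the fall of Mab21l4 goes with skin content was not tested.

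The shift of the sterol list with 1D11 was -0.870 (SE 0.138) and -0.893 (SE 0.183) with skin and muscle scores as covariates, which argues against those tissues. It was lower than that of proliferation genes, -0.0413 (SE 0.0969), by -0.828 (SE 0.123), which argues against lower proliferation. Over the 12 arrays, deviations of the sterol score from the group means correlated with those of the interferon score at r = -0.663 (permutation p = 0.0196) and rho = -0.657 (permutation p = 0.0333), with r = -0.494 without the 2 arrays farthest from the median. The values are consistent with a tie between sterol synthesis and the interferon response, as a hypothesis, and do not show which comes first.

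Hair follicle genes were tested, by a bound set beforehand, as a sign of skin left on the tumour pieces, which needed r over 0.7 with the keratinocyte score and was excluded under 0.3. Over the 12 arrays r was 0.0276 (permutation p = 0.930, rho = 0.203, permutation p = 0.527), and -0.173 without the 2 farthest arrays, which lies under the bound of 0.3. The hair follicle score spanned only -0.193 to 0.144, so it held little variation that could follow the keratinocyte score, and the test cannot decide. Seen afterwards, the keratinocyte scores fall into clusters of 6 and 6 arrays, within which r was 0.146 and 0.474, and 10 of the 18 hair follicle genes lay under the filter on low signal. The score of sebaceous gland genes, from -1.17 to 2.50, followed the keratinocyte score with r = 0.877, and that of melanocyte genes with r = 0.574. The source of the keratinocyte signal therefore stays open.

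Ctsg rose by 3.34 between RT+1D11 and isotype, while other azurophil granule genes, chosen after this was seen, were at 0.20 (Elane), -0.02 (Mpo) and 0.33 (Prtn3), with Elane and Mpo under the filter.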
